A study of Danio rerio with 31 samples.

How the data were processed

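The values analysed are the deposited log2 values, made by the authors with RMA and the Zv9 genome build, per the submitters' processing notes, which name no further steps. That the scale is log2 was read from the range of the values. Per the labels' protocols, total RNA was taken with Trizol from brain samples of individual fish, turned into cDNA with random hexamers, labelled with Cy3 and hybridized to 1-colour NimbleGen arrays. There are 31 arrays, 15 of telencephalon and 16 of midbrain, from 2 wild populations (Nadia and Pargana, which the sample titles call Pargana North and the protocol text Pargana) and 2 domesticated ones (Scientific Hatchery, Transgenic Mosaic 1), with 4 arrays per group and 3 for Scientific Hatchery telencephalon. All fish were aged 1 year; the telencephalon arrays come from 7 males and 8 females and the midbrain arrays from 7 males and 9 females. The number of arrays limits the precision. Array codes such as T21 and M21 in these texts are those of the labels, with T for telencephalon and M for midbrain. Hybridization batches, the dissection borders and whether the same number marks the same fish in both regions are not given in the sources used here. No scanner files were used.

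The table holds 15648 Ensembl genes and 1 row without a gene (0.00639% of rows), which was left out. Array medians lie between 9.57 and 9.74 and no rescaling was applied. Symbols matched 13251 of the gene IDs, and 2397 have none. Many symbols are written in capitals, as for human genes, and 1559 genes share a symbol with another. Genes named for a comparison are those past the threshold with a symbol that is not a clone or locus name (11335 genes qualify by symbol) and with the same sign in every population difference, the 10 largest in each direction, or 5 for the difference between regions. For the F tests they are the 8 with the largest F. Of each list up to 4 members with the smallest p could be named, besides members that passed. ENSDARG00000045097 is named outside this rule. Some genes that meet these rules are not reported here.

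The fit was limma with a mean for each of the 8 groups of region and population and a sex term in each region (21 residual degrees of freedom, prior 2.92). Contrasts were telencephalon minus midbrain, wild minus domesticated in each region and its difference between regions, male minus female in each region and its difference, and a moderated F test among populations. The Benjamini-Hochberg adjusted p threshold was 0.05. The contrasts, the threshold, the naming rule and the settings planned were chosen before the data were examined. The alternatives planned then were leaving out the dimmest genes, trend and robust moderation, array weights, averaging the rows of a symbol, no sex term, each region fitted alone, thresholds of 0.01 and of 2-fold, leaving out each population and each array, other scalings, and replicate numbers as a block. Settings added later left out arrays that correlate least, that are highest in eye or pituitary genes or that belong to Pargana 21, took the diencephalon score as a covariate, or changed the sex label of Pargana 21.

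Gene lists (26, written from general knowledge) were tested with camera at a preset correlation of 0.01 between genes and again with a correlation estimated per list, adjusted over the lists of a comparison. Entries were matched by symbol, then by an older symbol or without the paralog letter. Scores are mean values of a list relative to the region's mean. The analysis used R 4.3.3, limma 3.58.1 and statmod 1.5.0.

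A self-test put changes into 200 of 15648 simulated genes. The simulated noise was independent between arrays and between genes, with 1 SD per gene, and for differences among populations Nadia alone was shifted. Recovery in the real data may therefore differ. At log2 differences of 0.5, 1 and 2 it recovered 71.6%, 94.0% and 100% for the regions. Wild against domesticated gave 37.3%, 88.1% and 98.5% in telencephalon, 35.8%, 82.1% and 100% in midbrain and 11.9%, 61.2% and 92.4% for the difference between regions. For the sexes it was 49.3%, 82.1% and 98.5% in telencephalon and 32.8%, 85.1% and 98.5% in midbrain. For differences among populations it was 17.9%, 55.2% and 93.9% in telencephalon and 22.4%, 59.7% and 92.4% in midbrain.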

Results

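emx3, a transcription factor gene of the developing and adult forebrain, was higher in telencephalon than in midbrain by log2 5.84 (SE 0.12), from 15 telencephalon and 16 midbrain arrays. TBR1, EOMES and EMX1, which mark pallial neurons and their precursors, were higher by 4.81 (SE 0.25), 4.50 (SE 0.10) and 4.43 (SE 0.27). The peptide gene PYY (5.77, SE 0.19), the small GTPase gene GEM (5.05, SE 0.16), the Nogo receptor family gene rtn4rl2b (4.53, SE 0.21), the ciliary receptor gene GPR161 (4.30, SE 0.11) and arhgap4a (4.16, SE 0.17) also led on the telencephalic side. On the midbrain side, BARHL1 differed by -7.72 (SE 0.19), GATA3 by -6.11 (SE 0.15), SOX14 by -5.66 (SE 0.19) and IRX5 by -5.58 (SE 0.20). These 4 are transcription factor genes used in the midbrain and its neighbours. POU4F2 and pou4f4, factors of tectal and sensory neurons, differed by -5.78 (SE 0.25) and -5.94 (SE 0.16), TFAP2B by -6.13 (SE 0.12) and SHOX by -5.88 (SE 0.07). FAT2, a protocadherin gene of cerebellar granule cells, differed by -6.24 (SE 0.12), and pmchl, a hypothalamic peptide gene, by -6.22 (SE 0.45), so the midbrain samples carry transcripts typical of adjoining tissue.

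**Figure D1:**
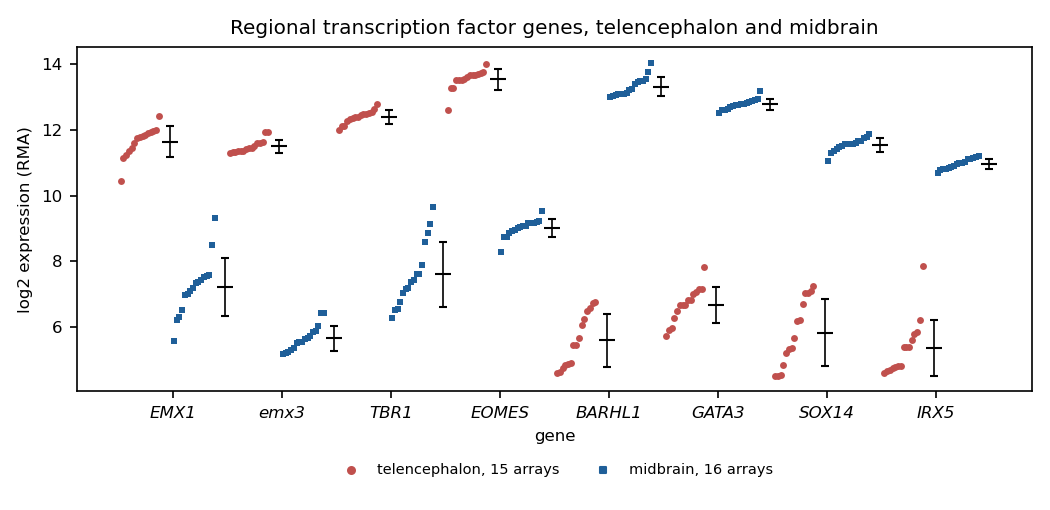
Deposited log2 values of 8 regional transcription factor genes, 1 point per array (15 telencephalon, 16 midbrain), with mean and SD beside each group.

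In all, 6828 of 15648 genes differed between the regions in limma at an adjusted p under 0.05, with 3377 higher in telencephalon and 3451 higher in midbrain. A 2-fold difference or more was reached by 1263 of them, 424 higher in telencephalon and 839 higher in midbrain. In 6408 of the called genes the difference had the same sign in all 4 populations. Tested in 1 population at a time, 2992 genes passed in Nadia, 3331 in Pargana (Pargana North in the sample titles), 2422 in Scientific Hatchery and 3165 in Transgenic Mosaic 1. Across genes, which are not independent replicates, each population's region difference correlated at 0.89 to 0.93 with the mean of the other 3.

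Among the 31 telencephalon regional genes, 18 rose and 11 fell relative to midbrain, LHX8 (3.63, SE 0.15) and LHX6 (3.398, SE 0.15) among those that rose. LHX9 (-2.08) and SLC17A7 (-1.96) were among those that fell, and the list as a whole passed (camera adjusted p = 0.0013) but not with its own correlation (adjusted p = 0.33 with an estimated correlation). Of the 28 midbrain regional genes, 24 fell and 1 rose, with PAX7 at -4.61 (SE 0.13), PAX2 at -3.52 (SE 0.09) and the exception SLC17A6 at 0.77 (SE 0.05). This list passed either way (adjusted p = 1.2e-19, and adjusted p = 0.0040 with an estimated correlation). Of 22 cerebellum and hindbrain genes 11 fell and 1 rose, led by the granule cell receptor gene GABRA6 (-3.96, SE 0.15), CALB2 (-2.22, SE 0.09) and cbln12 (-2.11, SE 0.15), adjusted p = 0.0013 for the list and adjusted p = 0.080 with an estimated correlation. The 20 diencephalon and hypothalamus genes split into 3 that rose, the forebrain factor FEZF2 among them, and 9 that fell, npvf (-3.74, SE 0.29) among them, without a list call (adjusted p = 0.082).

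Myelin genes were lower in telencephalon, with 10 of 15 oligodendrocyte and myelin genes down and 1 up: UGT8 (-2.85, SE 0.16) and plp1b (-2.57, SE 0.14) among them, adjusted p = 3.1e-07 and adjusted p = 0.066 with an estimated correlation. Vessel and connective tissue genes went the same way, with 20 of 28 endothelial, meningeal and fibroblast genes down and none up, DCN (-2.22, SE 0.21) and ALDH1A2 (-2.05, SE 0.23) among them (adjusted p = 3.6e-06, and adjusted p = 0.080 with an estimated correlation). Of 11 red blood cell genes 7 fell, with alas2 at -0.92 (SE 0.14) and SLC4A1 at -1.25 (SE 0.19), adjusted p = 0.0035 and adjusted p = 0.069 with an estimated correlation. In that list TAL1 (-2.91, SE 0.13) is also a factor of midbrain GABAergic neurons. The 27 microglia and leukocyte genes, 1 up and 9 down with tnfb at -1.51 (SE 0.11), did not pass as a list (adjusted p = 0.065). The 16 radial glia and astroglia genes went both ways, 4 up and 6 down, with SOX2 at 0.71 (SE 0.09) and nes at -1.98 (SE 0.11). Their adjusted p was 0.56, and their median of -0.04 changed sign when the arrays were shifted to the same median.

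Of 10 glutamatergic neuron genes 8 were higher in telencephalon and 2 lower (adjusted p = 0.0013, and adjusted p = 0.069 with an estimated correlation). This list shares EOMES, TBR1 and other members with the telencephalon regional list, so it does not test the transmitter type separately from the region. Of its glutamate transporter genes SLC17A8 (-2.68, SE 0.13) and SLC17A7 fell and SLC17A6 rose. Of 14 GABA-A and glycine receptor genes 2 rose, GABRA5 (1.23, SE 0.06) among them, and 9 fell, with glra4b at -1.90 (SE 0.12), adjusted p = 0.0086 and adjusted p = 0.12 with an estimated correlation. GABAergic neuron genes (4 of 13 up, 6 down) divided between DLX5 (2.12, SE 0.12), DLX2 (1.85, SE 0.16) and NPY (0.94, SE 0.07), which rose, and 6 that fell, adjusted p = 0.84. Among 17 ionotropic glutamate receptor genes GRIN2A fell (-2.78, SE 0.13) while GRIN2B (0.70, SE 0.05) and GRIA1 (0.70, SE 0.06) rose, 4 up and 9 down in all, adjusted p = 0.13. Among serotonin genes, the transporter SLC6A4 (-4.37, SE 0.21), TPH2 (-3.09, SE 0.40) and FEV (-1.95, SE 0.19) fell and the receptor htr7a rose by 3.12 (SE 0.12), 2 up and 6 down of 13, adjusted p = 0.11. Dopamine and noradrenaline genes, 6 up and 11 down of 21, included the receptors ADRA2C (2.03, SE 0.08) and adra2db (1.84, SE 0.10) on the telencephalic side and drd2l (-2.64, SE 0.15) on the other, adjusted p = 0.75.

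Neuropeptide genes marked both regions, 10 up and 16 down of 32, with rln3a at -5.22 (SE 0.15), npb at -2.49 (SE 0.18) and pyya at 1.86 (SE 0.12), adjusted p = 0.32. Among 10 pituitary hormone genes POMC (-3.37, SE 0.27) and gh1 (-1.66, SE 0.49) fell and smtlb rose by 2.04 (SE 0.28), 1 up and 4 down, adjusted p = 0.51. Of 27 immediate early genes 11 rose and 4 fell, led by egr2a (1.61, SE 0.12) and KLF4 (-1.57, SE 0.12), adjusted p = 0.24. The 32 circadian clock genes (6 up, 8 down, cry4 at -1.59, SE 0.14, adjusted p = 0.53) showed no common direction, nor did the 28 sex steroid and sex-determination genes (7 up, 6 down, NR0B1 at -1.49, SE 0.16, adjusted p = 0.71). The 24 cell cycle genes (3 up, 2 down, GMNN at 0.89, SE 0.11, adjusted p = 0.60) and the 27 stress axis and glucocorticoid genes (3 up, 8 down, sgk1 at -0.91, SE 0.06, and OXTR at -1.53, SE 0.18, adjusted p = 0.51) did not pass as lists either. The stress axis median of -0.03 turned positive under a same-median shift and under quantile normalization of all arrays. Ribosomal protein genes gave 13 up and 0 down of 54, RPL7L1 at 0.39 (SE 0.06) first, adjusted p = 0.064 for the list. By the same limma threshold 6828 of all 15648 genes (43.6%) passed, 3377 of them up, so passing is not particular to this list. The unadjusted p was under 0.05 for 7775 of all genes. Oxidative phosphorylation genes, 4 up and 11 down of 69 with COX4I2 at -0.39 (SE 0.07), had an adjusted p of 0.29, and under the same-median shift 9 were up and 2 down. Of 19 retina, lens and pineal genes only the melatonin enzyme gene aanat2 passed (1.78, SE 0.37; list adjusted p = 0.65). Of 45 MHC and interferon response genes 3 fell, cd74a (-0.40, SE 0.09), cd74b (-0.39, SE 0.09) and ciita (-0.38, SE 0.15), adjusted p = 0.85, while the same-median shift gave 3 up and 2 down.

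In telencephalon, crp3, of the acute-phase C-reactive protein family, was higher in wild than in domesticated fish by 2.59 (SE 0.40; 8 against 7 arrays), with means of 9.06 in Nadia, 9.11 in Pargana, 6.74 in Scientific Hatchery and 6.40 in Transgenic Mosaic 1. INHBA, which encodes an activin subunit, was higher by 1.55 (SE 0.22), and nmbb, a neuromedin B peptide gene, by 1.67 (SE 0.27). The metalloproteinase gene mmp20a (2.33, SE 0.31), the matrix protein gene mfap4.7 (1.87, SE 0.25) and the finTRIM gene ftr51 (1.56, SE 0.38) also rose. So did fam110a (1.43, SE 0.35), the zinc finger gene znf541 (1.25, SE 0.24), the receptor kinase gene mst1rb (1.25, SE 0.32) and the cannabinoid receptor gene CNR2 (1.203, SE 0.26). Among genes that fell were the opsin RRH (-2.69, SE 0.28), the myosin myo5ab (-2.08, SE 0.44), the meiotic spo11 (-1.86, SE 0.36) and the lysophosphatidic acid receptor LPAR2 (-1.76, SE 0.22). CA12, a carbonic anhydrase (-1.71, SE 0.27), AQP8, a water channel (-1.68, SE 0.35), NAALAD2, a glutamate carboxypeptidase family member (-1.66, SE 0.17), fbxo44.9 (-1.65, SE 0.40), the corticotropin receptor mc2r (-1.52, SE 0.27) and the nodal family gene spaw (-1.39, SE 0.32) fell as well. Of these, crp3, INHBA and nmbb passed in each of the 4 single differences between a wild and a domesticated population, as did ak9 and the unnamed gene ENSDARG00000045097.

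Altogether 299 genes passed in telencephalon, 130 higher and 169 lower in wild fish, of which 255 had the same sign in all 4 population differences and 95 differed at least 2-fold. The count depended on single populations and arrays: 548 without Scientific Hatchery, 116 without Transgenic Mosaic 1 and 176 without the telencephalon array of Nadia 7. It was 198 without the dimmest genes, 124 with the region fitted alone, 188 with the diencephalon list score as a covariate and 183 without the 4 arrays highest in eye genes. With 1 of the 31 arrays left out, the calls of mst1rb (11 of 31 times), ftr51 (7), fam110a (6) and fbxo44.9 (6) were lost. CNR2 lost its call without array T123 of Scientific Hatchery (adjusted p = 0.052), spaw without the same array (adjusted p = 0.073) and AQP8 without array T57 of the same population (adjusted p = 0.054). The covariate ended the calls of fam110a (adjusted p = 0.10), mst1rb (adjusted p = 0.056) and myo5ab (adjusted p = 0.064). Some calls rest on 1 population, without which the difference fell below 50% of its size, a bound chosen after the results were seen: mfap4.7 (0.33) and znf541 (0.28) without Nadia, mmp20a (0.15) and mst1rb (0.32) without Pargana, mc2r (-0.58) without Scientific Hatchery and RRH (-0.74) without Transgenic Mosaic 1.

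In midbrain, crp3 was again higher in wild fish, by 2.70 (SE 0.39; 8 against 8 arrays), and so were mfap4.7 (1.77, SE 0.24), the phosphatase gene ptpdc1b (1.74, SE 0.36) and ELAPOR1 (1.59, SE 0.23), a gene of endosomes and lysosomes. GALR2, a galanin receptor (1.32, SE 0.28), ms4a17a.10 (1.30, SE 0.25), ccdc125 (1.26, SE 0.30), the transcription factor mxd (1.26, SE 0.28), znf541 (1.19, SE 0.23) and znfl2a (1.16, SE 0.23) rose too. The respiratory chain subunit cox7a1 fell (-1.55, SE 0.26), as did NAALAD2 (-1.47, SE 0.16), the cartilage protein gene CILP2 (-1.18, SE 0.17), the lens factor foxe3 (-1.08, SE 0.21) and the vesicle transport gene bet1 (-1.004, SE 0.19). Smaller decreases were those of asgrl1 (-0.94, SE 0.23), the GTPase RHOH (-0.92, SE 0.21), rnf183 (-0.87, SE 0.15), the DNA helicase HELQ (-0.85, SE 0.13) and apol1 (-0.84, SE 0.14). In total 59 genes were higher and 64 lower, with 100 of the same sign in all 4 differences and 43 at least 2-fold. The count was 237 without Scientific Hatchery, 74 without Transgenic Mosaic 1, 194 without the 3 telencephalon arrays that correlate least with the others and 431 with array weights. With 1 array left out, asgrl1 lost its call 18 times of 31, ccdc125 15, RHOH 11, mxd 7 and GALR2 3, and the covariate ended the calls of ccdc125, mxd (adjusted p = 0.056 each) and RHOH (adjusted p = 0.052). The difference fell below 50% for mfap4.7 (0.31) and znf541 (0.21) without Nadia, for cox7a1 (-0.04), mxd (0.63) and RHOH (-0.38) without Scientific Hatchery and for ptpdc1b (0.37) without Transgenic Mosaic 1.

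The direction was shared by the 2 regions: 31 genes were higher and 38 lower in both, and 0 of the limma calls in 1 region passed in the opposite direction in the other (2404 and 1782 genes had an unadjusted p under 0.05). Of the 299 telencephalon genes 274 had the same sign in midbrain. A shared sign is not a shared size: in midbrain INHBA stood at 0.58 (SE 0.21) and nmbb at 0.005 (SE 0.26), and neither passed there. Replicate numbers recur in both regions, so the regions are not counted here as separate samples of the populations. In the limma test of a difference between the regions, 676 genes had an unadjusted p under 0.05, a share below 0.05 of all genes. A difference was called for 3 genes. The nucleotide kinase gene ak9 is 1 of them: it fell in telencephalon (-1.25, SE 0.15) and stood at -0.03 (SE 0.15) in midbrain, a difference of -1.22 (SE 0.21, adjusted p = 0.040). That call was lost in 23 of 31 fits with 1 array left out (adjusted p up to 0.14, without the telencephalon array of Scientific Hatchery 57). It was also lost with replicate numbers as a fixed block, as given in the closing part. The count of 3 became 1 without the dimmest genes. The self-test of this comparison recovered 61.2% of simulated 2-fold differences.

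Among 45 MHC and interferon response genes 2 of class II passed: mhc2dab (-1.78, SE 0.31) and mhc2daa (-1.38, SE 0.28) fell in wild telencephalon and again in midbrain (-1.73, SE 0.30, and -1.62, SE 0.27). Both are low in Nadia alone, and without Nadia the sign turned for mhc2dab (0.40 and 0.57) and mhc2daa (0.32 and 0.33). The thymidylate synthase gene TYMS fell in both regions (-1.09, SE 0.18, and -1.17, SE 0.17), a change carried by Transgenic Mosaic 1 (-0.10 and -0.05 without it). In telencephalon 2 more of the 24 cell cycle genes passed, CCNB1 (-0.85, SE 0.21) and GMNN (0.65, SE 0.16). Of 69 oxidative phosphorylation genes, cox7a1 fell (-1.54, SE 0.27) and NDUFB8 rose (0.42, SE 0.09) in telencephalon. The cox7a1 change is carried by Scientific Hatchery (means of 12.57 and 12.25 against 8.52 to 9.35 elsewhere), and without it the telencephalon value was 0.49, and that of NDUFB8 0.06. Of 32 neuropeptide genes, nmbb and pnocb (1.11, SE 0.24) rose in telencephalon, and mc2r alone of 27 stress axis and glucocorticoid genes fell. With the diencephalon list score as a covariate the calls of pnocb, CCNB1 (adjusted p = 0.11 each), GMNN (adjusted p = 0.075) and NDUFB8 (adjusted p = 0.091) ended.

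As lists, oxidative phosphorylation (adjusted p = 3.4e-04), ribosomal protein (adjusted p = 0.0068), neuropeptide and immediate early genes (adjusted p = 0.018 each) were shifted up in wild telencephalon, by medians of 0.11, 0.07, 0.18 and 0.21. None of these calls held beyond the preset correlation (adjusted p = 0.98 for each of the 4 lists with an estimated correlation). In midbrain, pituitary hormone genes (median 0.51) and retina, lens and pineal genes (median 0.62) were shifted up (adjusted p = 0.0042 each, and adjusted p = 0.99 for both with an estimated correlation). These 2 follow single arrays of wild fish: the pituitary score stood 2.07 and 1.48 above the region's mean in Pargana 85 and 13, and the eye score 1.60 and 1.26 above it in Nadia 98 and Pargana 21. The content of pituitary and eye transcripts therefore differed between samples. With p adjusted over the list alone, fshb (1.42, SE 0.39) and gh1 (2.14, SE 0.68) passed in the pituitary list and UGT8 (-0.81, SE 0.23) among the 15 myelin genes of telencephalon. With limma no member passed over all genes in 21 of the 26 lists in telencephalon and in 23 in midbrain.

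Other ways to pair the 4 populations called comparable numbers of genes. Pairing Nadia with Scientific Hatchery called 225 genes in telencephalon and 177 in midbrain, and pairing Nadia with Transgenic Mosaic 1 called 382 and 162, against 299 in telencephalon and, in midbrain, 59 higher plus 64 lower for wild against domesticated. Some of the genes behind these calls are set apart in 1 population: RRH stood at 9.89 in Transgenic Mosaic 1 and at 5.03 to 6.04 in the other telencephalon groups, and mmp20a at 8.65 in Pargana and 4.03 to 4.29 in the others. Across genes, which are not independent replicates, Nadia minus Scientific Hatchery correlated with Pargana minus Transgenic Mosaic 1 at -0.05 in telencephalon and -0.01 in midbrain. Nadia minus Transgenic Mosaic 1 and Pargana minus Scientific Hatchery gave 0.04 and 0.03. With 2 populations per class, the p-values measure spread between fish and not spread between populations, and a domestication effect is not separated here from population history.

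**Figure D2:**
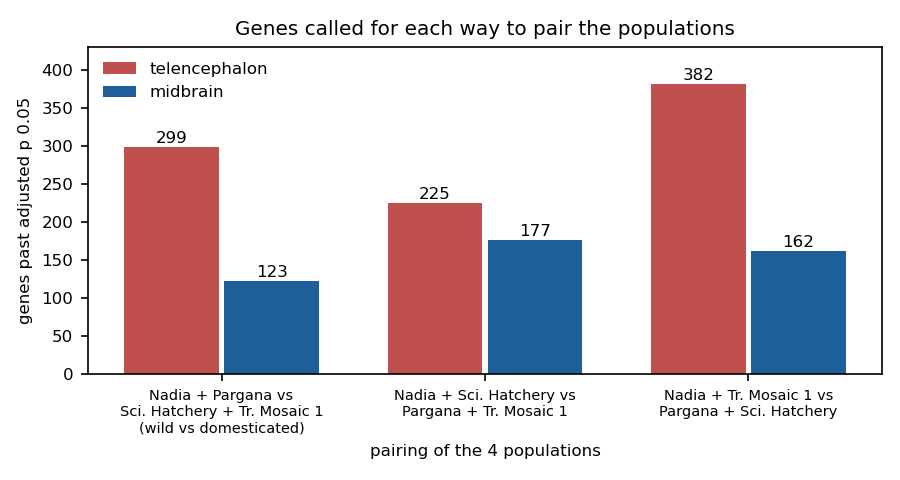
Genes past an adjusted p of 0.05 for each of the 3 ways to split the 4 populations into pairs, in telencephalon (15 arrays) and midbrain (16 arrays).

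Differences among the 4 populations reached 1008 genes in telencephalon and 515 in midbrain in the moderated F test. The counts were 623 and 324 without the dimmest genes and 552 and 304 without the 4 arrays highest in eye genes. Array weights gave 1503 in midbrain. With each region fitted alone the telencephalon count was 281, while the midbrain count stayed within 1.5 times of 515. Which region has more calls therefore depends on the fit. The kinetochore gene NSL1 came first in both regions (F = 110 and 72.2), with means of 9.56 and 8.83 in Transgenic Mosaic 1 and no mean above 5.61 elsewhere. RRH followed (F = 68.8 and 54.1). The metalloproteinase genes mmp20b (F = 56.99) and mmp20a (F = 56.8) were high in Pargana telencephalon, mmp20b at 10.38 against 4.84 to 5.22. The base excision repair gene UNG was highest in Pargana (10.83 in telencephalon, 8.92 in midbrain; F = 55.3 and 36.6), and C1QL4, a synaptic C1q family gene, in Transgenic Mosaic 1 (9.78, F = 48.8). mfap4.7 was high in Nadia alone (8.14 and 7.89; F = 47.04 and 43.3). mhc2dab was low there (6.97 and 6.91, against 10.82 to 11.55 elsewhere; F = 46.9 and 51.2), and so was mhc2daa in midbrain (7.74, F = 46.6). TYMS in midbrain was high in Transgenic Mosaic 1 (12.42, F = 45.7), and NAALAD2 rose step by step from Nadia (9.25) over Pargana (10.15) and Scientific Hatchery (10.86) to Transgenic Mosaic 1 (11.51, F = 35.4). The single differences in telencephalon ran from 156 genes (Nadia and Scientific Hatchery) to 859 (Pargana and Transgenic Mosaic 1), with 325 for the 2 wild and 254 for the 2 domesticated populations. In midbrain they ran from 68 (Nadia and Scientific Hatchery) to 264 (Pargana and Transgenic Mosaic 1), with 221 and 147 within the classes. Several of the genes named by F are set apart in 1 population. Sequence variants under the probes were not tested for them, so these differences in signal need not be differences in expression.

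**Figure D3:**
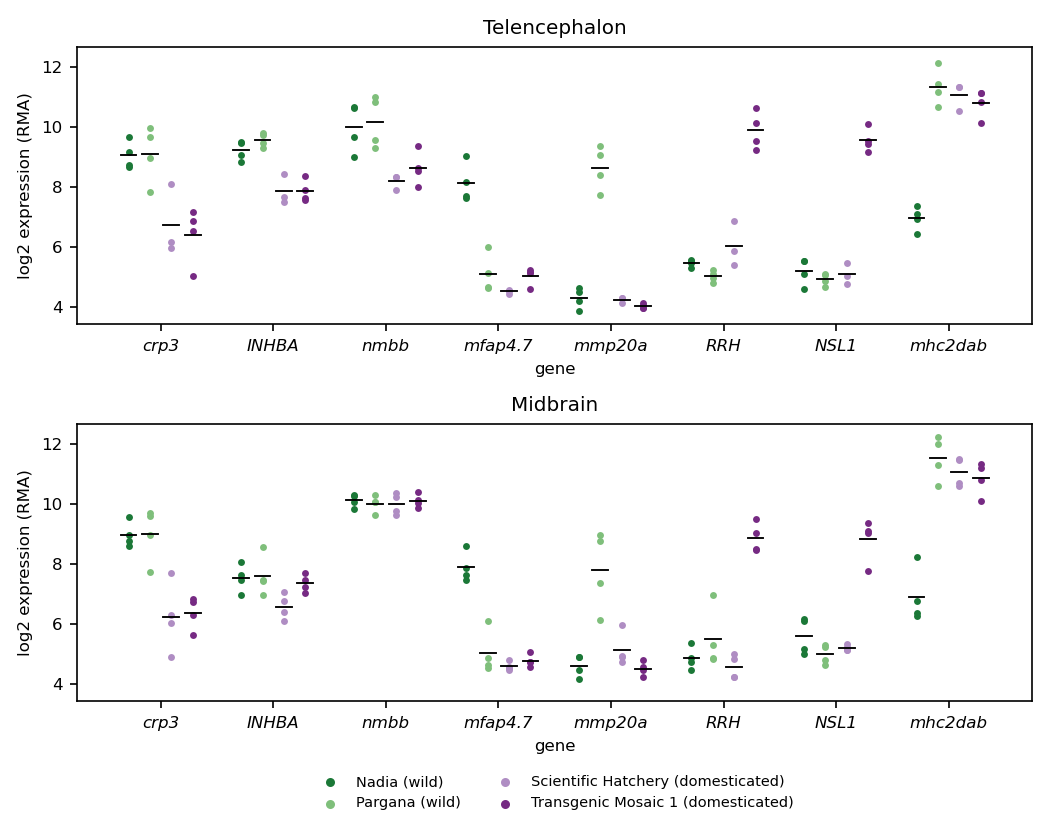
Deposited log2 values of 8 genes that differ among populations, 1 point per array (3 or 4 per population and region), with lines at the means.

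In males, DIO2, which encodes the deiodinase that activates thyroid hormone, was higher in both regions: by 1.85 in telencephalon (SE 0.23; 7 males, 8 females; adjusted p = 4.2e-04) and by 1.65 in midbrain (SE 0.23; 7 males, 9 females; adjusted p = 0.0026). In telencephalon HSD17B3, an enzyme gene of testosterone synthesis, was higher by 1.31 (SE 0.21), the growth factor gene IGF1 by 1.31 (SE 0.23), the G protein regulator gene RGS4 by 1.36 (SE 0.25) and the cholecystokinin gene CCK by 2.63 (SE 0.46). In midbrain IGF1 stood at 0.93 (SE 0.23) and did not pass (adjusted p = 0.57). These are all of the genes called by sex, 5 in telencephalon and 1 in midbrain, and limma called 0 for a difference of the sex effect between regions (515 at an unadjusted p under 0.05). CCK varied widely among female telencephalon arrays (SD 1.94, against 1.14 in males).

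The female Pargana 21 lay above the other females for DIO2 (10.79 in telencephalon, other females 9.09 to 9.80, lowest male 11.04; 11.66 in midbrain, other females 9.85 to 10.65, lowest male 11.62) and for HSD17B3 (11.28, others 9.59 to 10.30, lowest male 11.01). Without its telencephalon array 19 genes passed in telencephalon. Other telencephalon arrays moved the count of 5 as well: 14 without Pargana 85, 11 without Pargana 140, 3 without T99 of Transgenic Mosaic 1 or T123 of Scientific Hatchery, and 1 without T106 of Nadia. It was 2 without Nadia 98, Scientific Hatchery 47, Pargana 13, or T12 or T109 of Transgenic Mosaic 1. The midbrain count became 2 without the telencephalon array of Pargana 21 or of Pargana 140. DIO2 passed in both regions in each of the 31 fits without 1 array, while RGS4 lost its call in 25 of them, CCK in 10, IGF1 in 7 and HSD17B3 in 1 (adjusted p = 0.056 without T106). With the sex labels of Pargana 21 and 140 exchanged, the midbrain call of DIO2 ended (1.66, SE 0.30, adjusted p = 0.0503), and with the diencephalon list score as a covariate 0 genes passed in telencephalon, where DIO2 stood at 1.68 (SE 0.32) and IGF1 at 1.25 (SE 0.32). Chance regroupings of the sexes do not set the telencephalon count apart, as given in the closing part.

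**Figure D4:**
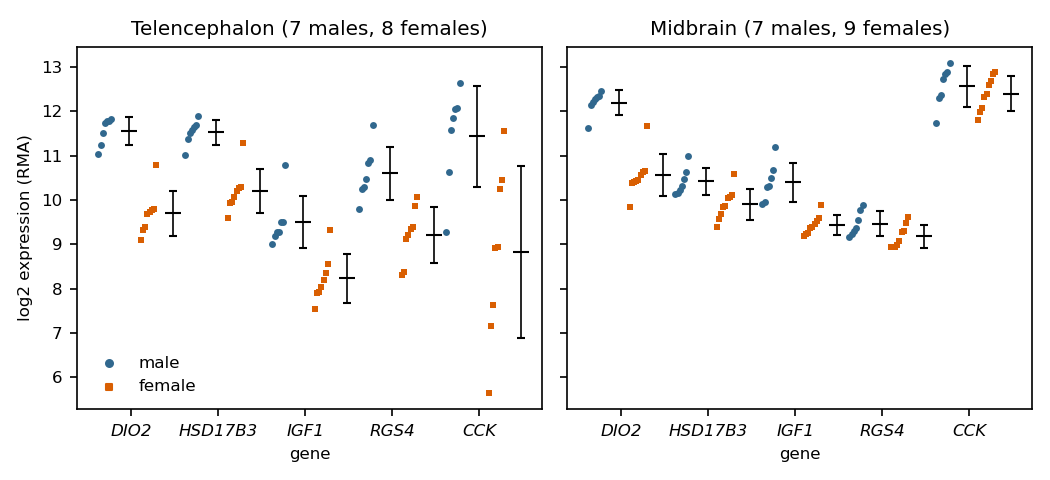
Deposited log2 values of the 5 genes called by sex in telencephalon, shown in both regions with mean and SD beside the points.

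Peptide and hypothalamic genes as lists were higher in male telencephalon: neuropeptide genes (median 0.42, adjusted p = 2.8e-07) and diencephalon and hypothalamus genes (median 0.50, adjusted p = 4.5e-05). Neither call held beyond the preset correlation (adjusted p = 0.36 and adjusted p = 0.49 with an estimated correlation). The 2 lists share members, avp and oxt among them, so their calls are not separate results in either region. With p adjusted over the list alone, HMX3 (2.47, SE 0.63), HMX2 (1.76, SE 0.48) and oxt (3.56, SE 1.12) passed in the hypothalamus list, 6 genes in all, and NTS (1.00, SE 0.27) and tac1 (0.66, SE 0.19) among 9 neuropeptide genes. The mean score of the hypothalamus list was 0.43 in males and -0.38 in females (exact permutation p = 0.026, unadjusted), and 5 of 8 females lay below the lowest male, a pattern that different shares of preoptic or hypothalamic tissue in the samples would also give. The permutation exchanged sex over all telencephalon arrays without regard to population. The list had passed camera in these same arrays, so this p is not separate support. In midbrain the same 2 lists went down in males (adjusted p = 0.0014 and 0.014; adjusted p = 0.78 for both with an estimated correlation), with 1 male, Scientific Hatchery 57, at a score of -1.91. GABAergic neuron genes were shifted up in male telencephalon (adjusted p = 0.022, and adjusted p = 0.49 with an estimated correlation), GAD1 (0.32, SE 0.09) among 3 that passed with p adjusted over the list alone.

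MHC and interferon response genes were shifted down in males in both regions (medians -0.10 and -0.13; adjusted p = 0.0061 and 0.0035), and no member passed over all genes, where 1681 and 647 genes had a limma unadjusted p under 0.05. This was lost too (adjusted p = 0.36 and adjusted p = 0.45 with an estimated correlation). Oxidative phosphorylation genes were shifted up in both (medians 0.06 and 0.05; adjusted p = 0.010 and 0.014), and these calls were lost as well (adjusted p = 0.88 and adjusted p = 0.78 with an estimated correlation). Of the 28 sex steroid and sex-determination genes HSD17B3 alone passed, and the list did not (adjusted p = 0.42 in telencephalon and 0.78 in midbrain).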

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

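Comparing the wild and domesticated calls with other pairings of the populations and with the gaps between population means, and the test of probe variants, were chosen after the results were seen, as were the fits with the hypothalamic score as a covariate and with changed sex labels. The bounds of the other tests in this part were set before the values they measure were seen, except where said.

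In 10 of 92 groups of arrays (10.9%) a lone array stood apart by Dixon's gap ratio, where chance does this in about 1 in 20 groups. Array T106 of Nadia was lowest of the wild fish for ftr51 (ratio 0.708) and AQP8 (0.669), and array T123 of Scientific Hatchery was lowest of the domesticated fish for AQP8 (0.596). In midbrain, Nadia 130 was lowest for ccdc125 (0.547) and Nadia 98 for foxe3 (0.590). Among males, T63 was highest for IGF1 (0.724; 10.78 against 9.01 to 9.50) and midbrain Pargana 140 lowest for DIO2 (0.612). Among females, Pargana 21 was highest for DIO2 in telencephalon (0.580) and midbrain (0.561) and for HSD17B3 in telencephalon (0.581). The wild against domesticated difference itself differed between regions for ak9 (-1.22), ENSDARG00000045097 (1.14, adjusted p = 4.3e-04) and si:ch211-161h7.5 (-3.01, adjusted p = 4.5e-06) in limma. The last of these stood at 9.89 in the telencephalon of Transgenic Mosaic 1 and at 4.51 to 5.34 in every other group.

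Genes called between wild and domesticated fish may reflect differences between populations unrelated to domestication: another pairing of the populations called 382 genes in telencephalon (299 for the real one) and 177 in midbrain (59 higher plus 64 lower). The widest gap between population means set 1 population apart in 66.9% of the called genes in telencephalon (95% interval 61.4 to 72.0). In midbrain it did so in 71.5% (63.01 to 78.77). Genes called by the other pairings gave 66.22% and 59.95% in telencephalon and 64.97% and 62.96% in midbrain, with overlapping 95% intervals. Of the 3 gaps between 4 means, 2 (66.7%) part 1 population from the rest, but this counts gaps and is not an expected share. The share expected without any pattern was not computed, so whether single populations carry the calls stays open. Sequence variants under the probes as the sole cause would give the same wild minus domesticated difference in both regions. ENSDARG00000045097 is expressed in midbrain (mean 10.06), and its difference between regions (1.14) passed without each array in turn (adjusted p up to 0.0019). Its differences in the regions are thus unequal, but the gene was chosen by this same test. The values are therefore no separate evidence against variants. For ak9 (-1.22) and si:ch211-161h7.5 (-3.01) variants cannot be told apart from other causes, since both are dim in midbrain (means of 6.91 and 4.66) and the ak9 call was lost in 23 of 31 fits without 1 array (adjusted p up to 0.14).

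Genes called by sex in telencephalon may partly follow the share of preoptic or hypothalamic tissue. With the hypothalamic score as a covariate, CCK went from 2.63 (SE 0.46) to 0.99 (SE 0.37, 95% interval 0.21 to 1.76) and DIO2 from 1.85 (SE 0.23) to 1.68 (SE 0.32). The call of DIO2 ended as its SE rose (adjusted p = 0.39, and 1.7e-08 to 0.39 over all alternatives). The score itself differs by sex (means of 0.43 in males and -0.38 in females), so the fit separates score and sex only in part. The DIO2 interval, from 1.02 upwards, excludes a fall below 0.93, or 50% of its size; the intervals were taken as bounds for all 5 genes after the values were seen, since the bound set beforehand for keeping a difference, an adjusted p under 0.05, was not met. CCK met the bound set beforehand for a tissue difference, a value under 50% of its size, but its interval reaches past it. CCK, HSD17B3 (1.31, SE 0.21, to 0.93, SE 0.26), IGF1 (1.31, SE 0.23, to 1.25, SE 0.32) and RGS4 (1.36, SE 0.25, to 0.74, SE 0.29) lost their calls, and their intervals include 50% of their size, so whether tissue explains them stays open, as does a sex difference in the hypothalamus itself.

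The fish Pargana 21, labelled female, may be a male. On 20 genes chosen without this fish, with DIO2 and HSD17B3 left out, it lay at 0.921 between the female mean (0) and the male mean (1) in telencephalon (other females up to 0.627, males from 0.450) and at 0.566 in midbrain (other females up to 0.327, males from 0.080), with 2 and 3 of 7 males below the highest other female, so the score does not separate the sexes fully. A wrong sex label gives both values; in telencephalon its high hypothalamic score (0.74) is a competing explanation, and a female with male-like expression was not tested. An exchange with the male Pargana 140 stays open. On these 20 genes 140 was the lowest male in both regions, and it was the lowest male for DIO2 in midbrain. There its DIO2 (11.62) still stood above every female but 21 (up to 10.65). In telencephalon every male stood above the females other than 21 for DIO2 (from 11.04, against up to 9.80) and HSD17B3 (from 11.01, against up to 10.30). The 80 genes that the exchange called in telencephalon (28 with 21 alone counted as male) may follow tissue or 1 poor array. The exchange moves a high hypothalamic score to the males and a lower one (0.17) to the females, and T140, the array of least correlation (0.959), gave 11 genes when left out. With the exchange the DIO2 SE was 0.30 in both regions and its midbrain call ended (1.66, adjusted p = 0.0503), whereas with 21 alone counted as male the SE was 0.15 (differences of 1.98 and 1.86).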

How the results depend on the processing

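The comparison of regroupings by the arrays of least correlation was chosen after the results were seen. Settings added then are those that leave out the arrays of least correlation, of eye or pituitary genes or of Pargana 21, the hypothalamic covariate and the changed sex labels. Counts are given as wild against domesticated (WD), sex and populations, in telencephalon (tel) and midbrain (mid), where they moved by over 1.5 times; the cause was not tested.

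Without the dimmest genes, WD was 198 in tel and 1 for the difference between regions, and populations 623 in tel and 324 in mid. Trend and robust moderation gave 8 for sex in tel. Array weights gave WD 431, sex 2 and populations 1503 in mid. Each region fitted alone gave WD 124, sex 1 and populations 281 in tel and sex 2 in mid. An adjusted p under 0.01 left WD 110 and 52, sex 1 in tel and populations 344 and 203; a 2-fold threshold left 1263 for the regions and WD 95 and 43. WD became 548 and 237 without Scientific Hatchery and 116 and 74 without Transgenic Mosaic 1. Without Nadia the sign turned for mhc2dab (0.40 in tel, 0.57 in mid) and mhc2daa (0.32 and 0.33), and without Scientific Hatchery for cox7a1 in tel (0.49). Without the 3 tel arrays of least correlation, WD was 194 and sex 2 in mid. The hypothalamic covariate gave WD 188 in tel and sex 0 in tel (limma; 1681 genes at an unadjusted p under 0.05 without the covariate) and 2 in mid. Without the 4 arrays highest in eye genes, WD was 183 and sex 1 in tel, and populations 552 and 304; without 2 pituitary-rich arrays sex was 2 in tel. Without the arrays of Pargana 21 sex was 15 in tel and 2 in mid; counted as male it gave 28 in tel, and exchanged with Pargana 140, 80 and 2. Leaving out 1 array gave 6528 to 6768 for the regions, WD 176 (without tel Nadia 7) to 345 in tel, 90 to 152 in mid and 2 to 4 for the difference between regions. For sex it gave 1 (without T106) to 19 (without T21) in tel and 1 to 2 in mid (2 without T21 or T140), and for populations 784 to 1093 and 353 to 608. Of the values of named WD genes under the other settings, 484 of 572 in tel and 416 of 473 in mid stayed past the threshold in the same direction, and 85 and 55 kept the direction without passing; for sex in tel 61 of 80 stayed past it.

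Of 100 regroupings of the arrays, the real one included, 1 called as many genes for the regions (6828, highest other 9). The same held for WD in tel (299, highest other 99) and mid (59 plus 64, highest other 10). It held too for populations in tel (1008, highest other 113) and mid (515, highest other 6). Chance is excluded for all of these. For WD this excludes only that the populations are alike, as fish were regrouped across populations. For the difference between regions 1 regrouping did as well (real 3, highest other 1), but a real count of 3 genes does not exclude chance. For sex in mid 3 did (real 1, highest other 2). That is under the bound of 5 of 100 set beforehand, but with a real count of 1 gene it does not exclude chance. For sex in tel 6 did (real 5, highest other 459), so chance is not excluded, and the regrouping with 459 genes points to a structure of the samples, which was not identified. Regroupings with the 3 tel arrays of least correlation on the same side reached the real count in 2 of 13 cases, against 3 of 86 otherwise (Fisher exact p = 0.13; the regrouping with 459 genes, which prompted this test, is among the 13). Replicate numbers met the pairing criterion for 13 of 15 pairs, all but T98 and T106 of Nadia, and 12 of 15 tel arrays correlated best with their own number; the criterion asks for every pair, so the block fits are alternatives here (random block: 7634 for the regions, WD 308 and 150, 4 for the difference between regions, sex 7 and 1, populations 1055 and 601; fixed block: 7454 for the regions and 3 for the difference between them, ak9 with an adjusted p of 0.053). Over all genes these 2 correlate more when crossed (0.16 and 0.23) than straight (0.05 and 0.07). On 500 genes chosen from the other pairs the order turns (straight 0.72 and 0.68; crossed -0.02 and 0.06; margin -0.742), which an exchange of their numbers would not give; why the crossed values are higher over all genes was not tested.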

Other observations

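The observations of this part were chosen after the results were seen, except for the single-population differences, and each is a hypothesis.

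In telencephalon, with p adjusted over the list alone, the preoptic peptide genes avp (2.07, SE 0.72) and oxt (3.56, SE 1.12) were higher in males, as was OTP (0.74, SE 0.26), which specifies the neurons that make them. These 3 genes help to form the hypothalamic score, so a fit with that score as a covariate does not test them. SOX14, a factor of diencephalic and midbrain neurons outside the score, went from 1.36 (SE 0.28) to 0.35 (SE 0.22) with the covariate. Whether these genes differ between the sexes or follow the tissue in the samples stays open. The serotonin transporter gene SLC6A4, lower in males with p adjusted over the list alone (-0.98, SE 0.30), stood at -1.07 (SE 0.41) with the covariate. It did not pass over all genes either with or without the covariate.

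Of 32 circadian clock genes 5 passed between wild and domesticated midbrain with p adjusted over the list alone, 1 higher and 4 lower in wild fish, among them CLOCK (-0.37, SE 0.10), NFIL3 (-0.48, SE 0.13), bmal2 (-0.78, SE 0.25) and dbpa (0.59, SE 0.20). The list was not shifted (adjusted p = 0.98), and none of these genes passed limma over all genes (adjusted p from 0.097 to 0.20; 1782 genes at an unadjusted p under 0.05 in this comparison). The hour of sampling is not given in the sources used here.

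crp3 was higher in both wild populations in both regions and passed each single difference between a wild and a domesticated population, 5 genes doing so in telencephalon and 1 in midbrain. Other pairings gave 2 and 7 such genes in telencephalon and 0 and 4 in midbrain, so such a set also arises from populations paired without regard to domestication. INHBA and nmbb passed in telencephalon only, with midbrain differences of 0.58 (SE 0.21) and 0.005 (SE 0.26). Further wild and domesticated populations, measured for crp3 in both regions and for INHBA and nmbb in telencephalon, would test whether these genes follow domestication.

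DIO2 was higher in both regions in the fish labelled male, though its midbrain call ended with the labels of Pargana 21 and 140 exchanged, and a higher local activation of thyroid hormone in male brains may follow; the covariate fit left it at 1.68 in telencephalon. Measuring DIO2 in separately dissected hypothalamus and pallium of both sexes, with genotyped or gonad-checked fish including a second look at Pargana 21, would test it.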
